A study of Mus musculus with 8 samples.

How the data were processed

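RNA of LLC1 and MLE12 cells was analysed in 4 libraries per line, 8 in all. Per the labels' protocols, poly-A RNA was selected, fragmented and copied with random primers, fragments of about 250 to 300 bp were taken from gels and amplified by PCR, and paired-end reads of 100 nt were sequenced on an Illumina instrument. The protocol names no step that marks the strand. The deposited table holds raw counts per gene for 43346 Ensembl mouse gene IDs with gene name, position and a length. Per the submitters' processing notes CASAVA, TopHat2, featureCounts and edgeR were used with genome build mm10. Versions, the strand setting, the treatment of reads with several alignments and the annotation release were not given in the sources used here. A count of 2 was more frequent than a count of 1 in every library (1392 against 1130 genes in LLC1 replicate 1), the pattern that appears when both mates of a pair are counted. All 37 genes of the mitochondrial chromosome were at 0 in every library, so its transcripts were not analysed here. Of the 43346 genes, 13936 had no count in any library. Gene IDs were looked up in GENCODE release M21 of the same build for biotypes and GC content. Of the IDs, 42462 (98.0%) matched, and of these 78.9% had the same chromosome, start and end. Chromosome names and coordinates are those of the deposited table. The counting strand is not stated, so reads of overlapping and antisense genes cannot be told apart. Of the list members tested, 7 had no count in one line; their fitted fold changes are no bounds, and with these members set to the bound of 3 counts over the line's libraries 0 list medians moved. Where a name belonged to several gene IDs (127 genes), the ID with the most counts was used for the lists.

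Groups were taken from the cell line in the labels. The labels do not say whether the 4 libraries of a line came from separate cultures, so p-values measure the spread between these samples, which may be technical. No library was a copy of another: chi-square per degree of freedom between libraries of one line was 6.81 to 58.4. Library totals were 46.8, 55.3, 49.8 and 52.5 M counts for LLC1 and 74.0, 72.5, 76.7 and 48.6 M for MLE12. A count of 0 allows up to 3 counts, and such floors cover counting error only, since the reads were amplified by PCR without molecular identifiers and mates appear to be counted separately.

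Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with cell line as the group, libraries were scaled by TMM (factors 0.924 to 1.04), and glmQLFit with robust estimation and glmQLFTest compared LLC1 with MLE12 without covariates. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05. A second test, glmTreat, was run against a fold change of 2. CPM values use the scaled library sizes, except that detection in one line, the levels of the 2 genes given for it, residual shares and the levels allowed by a count of 0 use plain library totals. The SE of a log2 fold change is its size divided by the square root of its F statistic. The 26 gene lists were tested with camera (limma 3.58.1, preset correlation 0.01) where at least 5 members were tested, which held for 25. A shift was called for 11 lists, and with the correlation estimated for each list the alveolar type I list alone was called. Detection in one line only was defined as at least 1 CPM in every library of that line and at most 3 counts over the 4 libraries of the other, with no test.

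The test design, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. By that rule the text names, per direction, the 10 genes with the largest log2 fold changes among called genes of at least 50 CPM in the higher line with no overlap between lines, leaving out gene models named by number. From each list it takes up to 3 called members per direction with the largest changes and at least 10 CPM in the higher line; the first of these are given. It always names Sftpc, Sftpb, Nkx2-1, Cdh1, Epcam, Vim, Cdh2, Trp53, Cdkn2a, Rb1, Myc, Cdkn1a, B2m, H2-K1 and Xist, and the 5 genes with the most counts in each line. Genes named outside it are said to be chosen after their values were seen. Some genes picked by this rule, and tests on 1 of them, are not reported here.

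Counts were simulated for the same 18546 genes with the MLE12 means in both lines. The 200 changed genes, balanced in direction, were drawn from those above 1 CPM. The LLC1 against MLE12 fit called 47 of 50 genes changed 1.5-fold and all 50 each at 2-fold, 4-fold and 8-fold, and 12 of 18346 unchanged genes. With so few changed genes the simulation cannot show how the fit does where 81.6% of genes were called, or for changed genes of low counts. Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors, upper-quartile factors, library totals alone, no filter, a filter of at least 1 CPM in 4 libraries, removal of the 20 most abundant genes, each library left out in turn, the replicate number as a block, camera with estimated correlations, and fry. After the data had been seen, a subtraction of residual reads from the other line and a detection limit relative to the other line's level were added. Residual shares were measured in each library on the 25 genes of at least 100 CPM in the other line that had the lowest relative level in the remaining libraries of the line. Intervals of window medians come from 1000 bootstrap draws of the genes in a window. Chromosome and neighbour comparisons were made in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.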

Results

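The series measured messenger RNA in 2 mouse cell lines grown without any added reagent to about 80% confluence. LLC1 is the Lewis lung carcinoma line, which came from a lung tumour of a C57BL mouse. MLE12 is a lung epithelial line made from a tumour of a transgenic mouse that carried the SV40 large T antigen under the surfactant protein C promoter. There were 8 libraries, 4 of each line, and the deposited table held raw counts for 43346 genes. Library totals ran from 46.8 to 55.3 M counts in LLC1 and from 48.6 to 76.7 M in MLE12. A count of 0 in a library allowed a level of up to 0.0641 CPM, counts scaled to a common library size, in the shallowest library and 0.0391 CPM in the deepest. Levels are given as mean ± SD in CPM (n = 4 per line). Log2 fold changes, ± SE, are LLC1 over MLE12, so that positive values are higher in LLC1. Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

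The comparison asks which transcripts differ between the carcinoma line and the lung epithelial line. Col3a1, Fgfr1, Myc, Hmga2 and Spp1 were higher in LLC1. The alveolar genes Nkx2-1, Sftpc and Sftpb, the epithelial cadherin gene Cdh1 and the tumour suppressor Cdkn2a were higher in MLE12. Of the 18546 genes tested, 15132 (81.6%) passed the adjusted p threshold of 0.05, 7554 higher in LLC1 and 7578 higher in MLE12. Many of these differences were small: 4667 of the called genes differed by less than 1.5-fold. Tested against a minimum fold of 2, 3100 genes were higher in LLC1 and 3143 higher in MLE12, together 33.7% of the genes tested. The share over 2-fold was 34.5% of 13805 protein-coding genes and 41.7% of 521 lincRNA genes. Replicates lay close together, with a biological coefficient of variation of 7.10%. Pearson's r of log CPM across genes, which are not independent replicates, was 0.991 to 0.995 within a line and 0.777 to 0.791 between the lines.

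Among genes of at least 50 CPM in one line, those with the largest log2 fold changes toward LLC1 were Apbb1ip (9.95 ± 0.09), Nefl (9.59 ± 0.13), Gng2 (9.45 ± 0.11), Epb4.1l3 (9.39 ± 0.13), Adcyap1r1 (9.35 ± 0.14), Rhox5 (9.32 ± 0.12), Olfm1 (9.29 ± 0.10), Dkk2 (9.26 ± 0.12), Thbs2 (9.26 ± 0.10) and Gatm (9.20 ± 0.13). Apbb1ip, an adaptor of Rap1 signalling to integrins, stood at 86.2 ± 2.62 CPM in LLC1 and 0.0847 ± 0.0156 CPM in MLE12 (adjusted p = 1.0e-23). Rhox5, a homeobox gene of the X-linked reproductive cluster, reached 362 ± 17.4 CPM in LLC1 and 0.577 ± 0.20 CPM in MLE12. Thbs2, a matricellular protein, stood at 306 ± 11 CPM in LLC1 and 0.523 ± 0.197 CPM in MLE12. The Wnt antagonist Dkk2 was at 219.5 ± 1.69 CPM in LLC1 and 0.384 ± 0.202 CPM in MLE12. Nefl, the light neurofilament subunit, stood at 56.5 ± 2.99 CPM in LLC1 and 0.0720 ± 0.0376 CPM in MLE12. Toward MLE12 the largest were Trabd2b (-8.69 ± 0.10), Serpinb1a (-8.63 ± 0.11), Nrep (-8.60 ± 0.17), Epha4 (-8.49 ± 0.09), Adora1 (-8.48 ± 0.11), Fat4 (-8.40 ± 0.16), Clic5 (-8.39 ± 0.11), Mpzl2 (-8.35 ± 0.10), Ffar4 (-8.32 ± 0.11) and Cyp1b1 (-8.29 ± 0.13). Cyp1b1, a cytochrome P450 of xenobiotic and steroid metabolism, stood at 1.46 ± 0.516 CPM in LLC1 and 450.3 ± 21.8 CPM in MLE12 (adjusted p = 7.4e-15). The protease inhibitor Serpinb1a has close paralogs, so the split of its reads is uncertain. Genes of at least 100 CPM in one line kept a small residual share in the other. The lowest share was 0.301% in LLC1 (Cyp1b1, of 2432 genes) and 0.171% in MLE12 (Rhox5, of 2094 genes). If such counts are reads of the other line, the differences of these genes are understated and their order is uncertain.

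**Figure D1:**
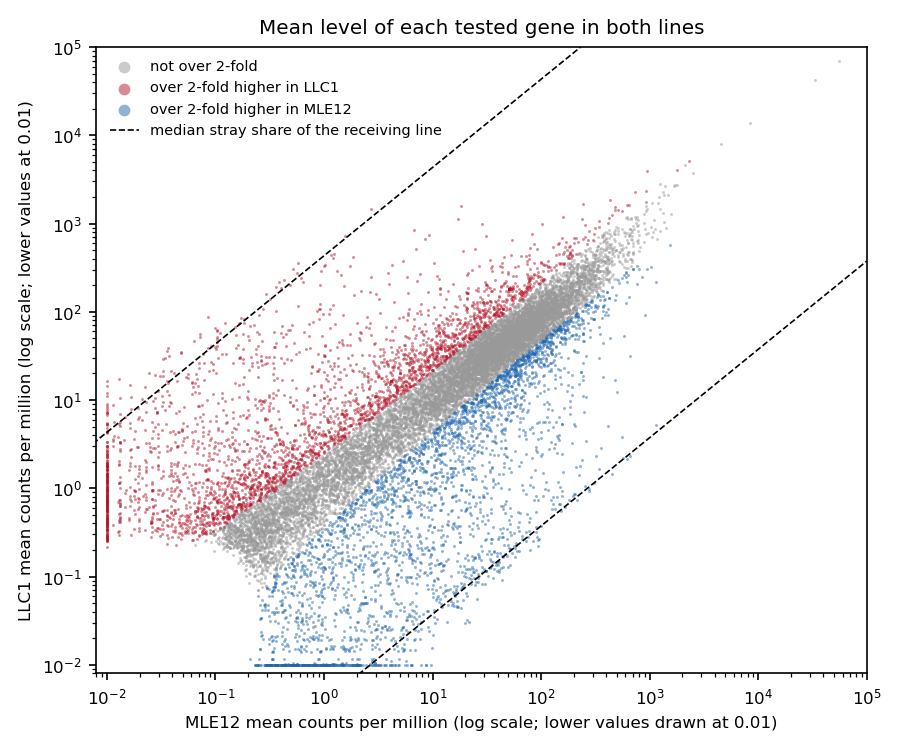
Mean CPM of each tested gene in MLE12 (x axis, log scale) and LLC1 (y axis, log scale), n = 4 libraries per line; red and blue points passed the test against a minimum fold of 2. Dashed lines mark the median residual share, 0.374% of the MLE12 level in LLC1 and 0.232% of the LLC1 level in MLE12, along which the abundant line-restricted genes lie.

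The alveolar marker genes with enough counts to be tested were mostly higher in MLE12. Nkx2-1, the transcription factor of lung epithelial identity (ENSMUSG00000001496, chromosome 12, 56531958 to 56536908, mm10), stood at 0.664 ± 0.109 CPM in LLC1 and 147 ± 6.39 CPM in MLE12, with a log2 fold change of -7.79 ± 0.08 (adjusted p = 3.0e-23). The surfactant protein gene Sftpc stood at 0.154 ± 0.0549 CPM in LLC1 and 23.6 ± 1.60 CPM in MLE12 (-7.26 ± 0.14). Sftpb, another surfactant protein gene, stood at 0.312 ± 0.0255 CPM in LLC1 and 32.4 ± 1.08 CPM in MLE12 (-6.68 ± 0.10). The 14 tested alveolar type II and surfactant genes, of 20 listed, comprised 3 higher in LLC1, 10 higher in MLE12 and 1 not called (3 and 10 adjusted over the list alone). Members with too few counts to be tested, named after their values were seen, were Sftpa1, Sftpd, Slc34a2, Lamp3, Lyz2 and Hc. Over the MLE12 libraries these had 7, 0, 1, 21, 36 and 0 counts, so they were near or at the floor in MLE12 too. The list median was -2.70 (camera adjusted p = 0.0109, adjusted p = 0.174 with an estimated correlation). The exceptions in that list included the fatty acid binding protein Fabp5 (6.77 ± 0.14), which shares reads with processed pseudogenes and is uncertain, and the transcription factor Etv5 (1.40 ± 0.04). Alveolar type I genes were also higher in MLE12. The 14 tested members comprised 2 higher in LLC1, 11 higher in MLE12 and 1 not called (2 and 11 adjusted over the list alone). Their median log2 fold change was -2.06 (camera adjusted p = 3.2e-10, adjusted p = 0.0335 with an estimated correlation). The chloride channel protein Clic5 (-8.39 ± 0.11) and the insulin-like growth factor binding protein Igfbp2 (-8.22 ± 0.07) were among those higher in MLE12, and Sema3e (0.27 ± 0.04) was higher in LLC1. Among 8 airway secretory, basal and ciliated genes tested, of 17 listed, there were 1 higher in LLC1, 6 higher in MLE12 and 1 not called (2 and 6 adjusted over the list alone). Their median was -3.27, without a call against the other genes (camera adjusted p = 0.398). The mucin gene Muc5b (14.9 CPM in MLE12) had a log2 fold change of -4.75 ± 0.15. The other members higher in MLE12 stood at only 0.347 to 1.08 CPM there. Lung lineage transcription factors went both ways, with 9 higher in LLC1, 12 higher in MLE12 and 3 not called (10 and 12 adjusted over the list alone). The median of the list stood at -0.47 (camera adjusted p = 0.0255, adjusted p = 0.331 with an estimated correlation). Foxp2 (-7.81 ± 0.13) joined Nkx2-1 on the MLE12 side, while Etv4 (2.14 ± 0.04) and Sox9 (1.80 ± 0.07) were higher in LLC1.

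**Figure D2:**
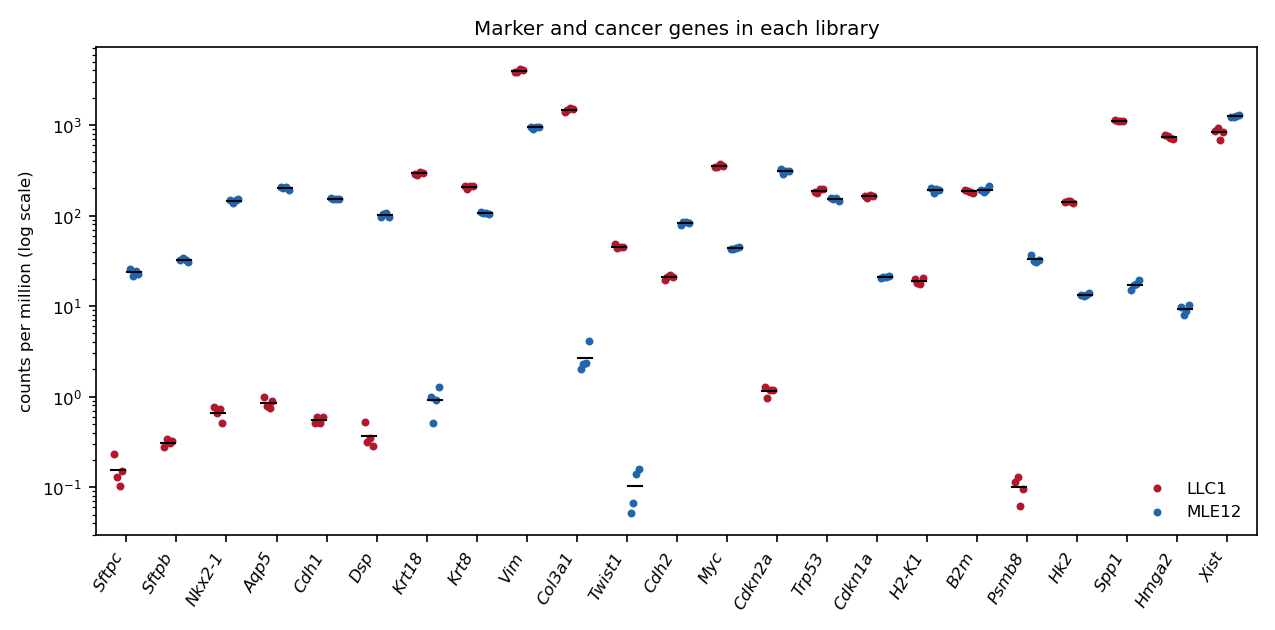
CPM of 23 named genes in each of the 8 libraries (y axis, log scale; n = 4 per line), red for LLC1 and blue for MLE12, with a black bar at each mean. The 4 libraries of each line lie apart from those of the other line for every gene shown except B2m, whose means were 185 and 194 CPM.

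Epithelial junction genes were mostly higher in MLE12 and mesenchymal genes mostly higher in LLC1. Cdh1, which encodes E-cadherin (ENSMUSG00000000303, chromosome 8, 106603351 to 106670246), stood at 0.553 ± 0.0474 CPM in LLC1 and 154 ± 3.05 CPM in MLE12, a log2 fold change of -8.11 ± 0.07. The 33 tested epithelial junction, keratin and identity genes comprised 8 higher in LLC1, 25 higher in MLE12 and 0 not called (8 and 25 adjusted over the list alone). Their log2 fold changes had a median of -4.48 (camera adjusted p = 9.2e-08, adjusted p = 0.0771 with an estimated correlation). The median member, Tjp3, stood at only 0.168 CPM in LLC1 and 3.88 CPM in MLE12. Members higher in MLE12 ranged widely there, from low (Dsg2 0.313 and Krt7 2.92 CPM) to abundant (Dsp 101 and Jup 240 CPM). These members were chosen after their values were seen. The claudin Cldn3 (-8.18 ± 0.22) lay with Cdh1, and Epcam was low in both lines (0.0235 ± 0.0282 CPM in LLC1 and 3.36 ± 0.177 CPM in MLE12; -6.94 ± 0.34). Keratin genes divided. Krt18 stood at 293 ± 9.03 CPM in LLC1 and 0.930 ± 0.315 CPM in MLE12 (8.34 ± 0.12), and its partner Krt8 was also higher in LLC1 (0.97 ± 0.04). Krt19, chosen after its values were seen, was higher in MLE12 (-7.19 ± 0.07). The plakophilin gene Pkp3 (8.26 ± 0.18) was higher in LLC1. Among 32 mesenchymal genes, the counts were 21 higher in LLC1, 11 higher in MLE12 and 0 not called (21 and 11 adjusted over the list alone). The list median was 1.54 (camera adjusted p = 1.4e-04, adjusted p = 0.0879 with an estimated correlation). The collagen gene Col3a1 (1478 ± 59.1 CPM in LLC1 and 2.70 ± 0.969 CPM in MLE12; 9.15 ± 0.19) and the transcription factor Twist1 (8.79 ± 0.13) were higher in LLC1. The intermediate filament gene Vim stood at 3960.2 ± 154 CPM in LLC1 and 943 ± 21.2 CPM in MLE12 (2.07 ± 0.05). MLE12 had more of the collagen gene Col1a1 (-5.79 ± 0.11), the matrix glycoprotein gene Tnc (-3.00 ± 0.11) and Cdh2. The latter encodes N-cadherin and stood at 20.8 ± 1.03 CPM in LLC1 and 82.8 ± 2.33 CPM in MLE12 (-1.99 ± 0.05). Matrix protease, plasminogen system and inhibitor genes included 16 higher in LLC1, 10 higher in MLE12 and 1 not called (16 and 10 adjusted over the list alone) of 27 tested. For the list as a whole the median was 0.81 (camera adjusted p = 0.218). The protease genes Mmp3 (8.78 ± 0.11) and Adamts1 (3.56 ± 0.11) were higher in LLC1, and the inhibitor Timp3 (-7.71 ± 0.11) and the protease Mmp2 (-6.66 ± 0.11) higher in MLE12. Integrin and matrix receptor genes were divided, with 7 higher in LLC1, 15 higher in MLE12 and 2 not called (7 and 15 adjusted over the list alone). Their median log2 fold change was -1.04 (camera adjusted p = 0.721). Itgb7 (7.79 ± 0.08) and Itga6 (673 ± 17.8 CPM in LLC1 and 8.52 ± 1.13 CPM in MLE12; 6.31 ± 0.07) were higher in LLC1, and the laminin receptors Bcam (-4.83 ± 0.17) and Dag1 (-2.14 ± 0.05) higher in MLE12.

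**Figure D3:**
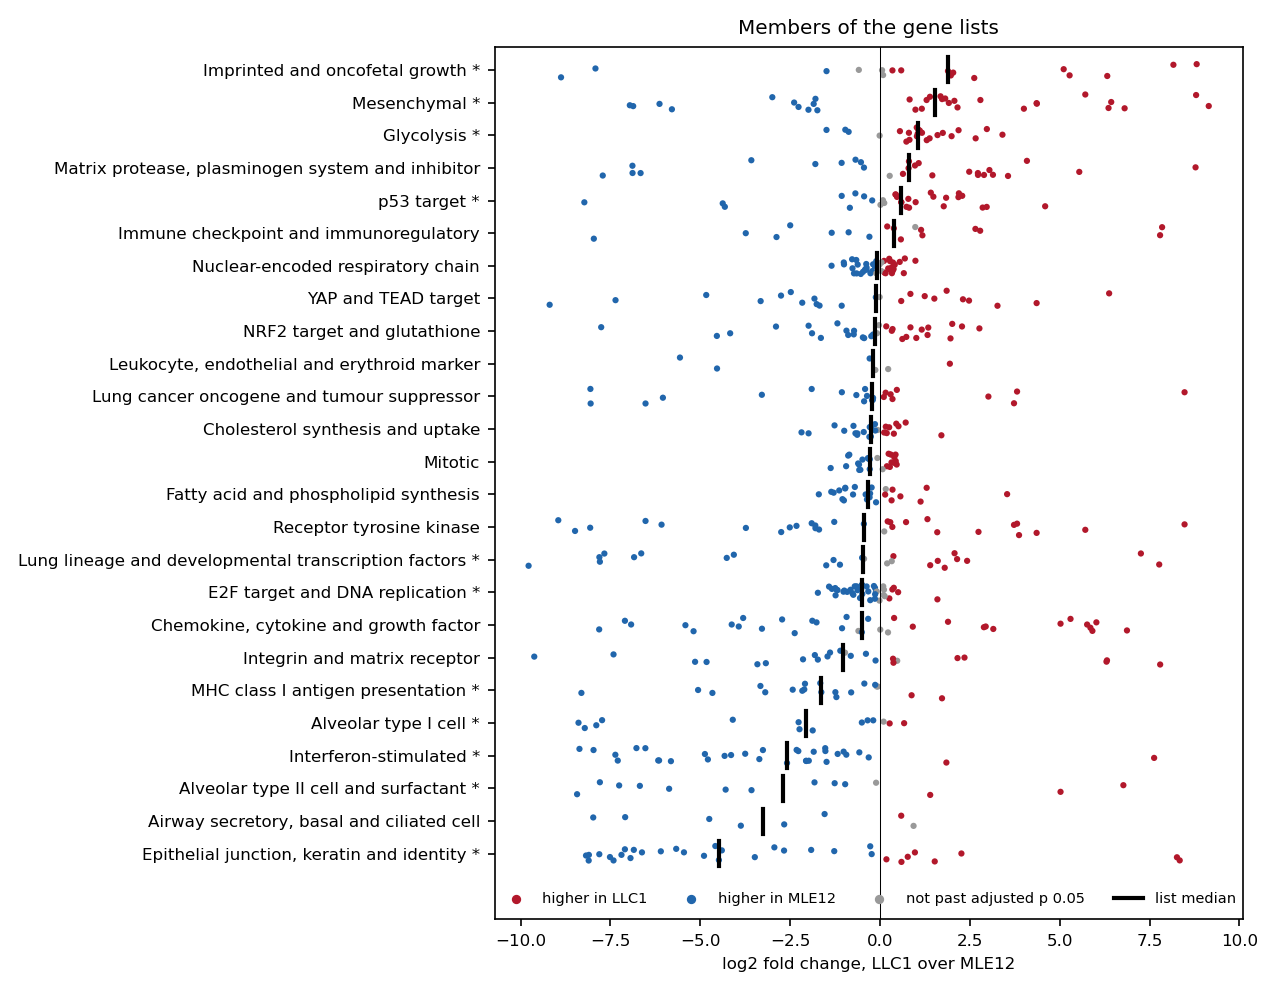
Log2 fold change, LLC1 over MLE12 (x axis), of each tested member of the 25 gene lists with at least 5 tested members, 1 point per gene, with a black bar at each list median; an asterisk marks the 11 lists with a camera adjusted p under 0.05. Medians run from -4.48 for epithelial junction genes to 1.89 for imprinted and oncofetal genes.

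Oncogenes and tumour suppressors differed in both directions. Myc (ENSMUSG00000022346, chromosome 15, 61985341 to 61990374) stood at 353 ± 12.2 CPM in LLC1 and 43.7 ± 0.882 CPM in MLE12 (3.02 ± 0.04). Cdkn2a, the locus of the p16 and Arf cell cycle inhibitors (ENSMUSG00000044303, chromosome 4, 89274471 to 89294653), stood at 1.16 ± 0.130 CPM in LLC1 and 307 ± 16.8 CPM in MLE12 (-8.05 ± 0.08). Its neighbour Cdkn2b was at 0.127 ± 0.0296 CPM in LLC1 and 34.2 ± 2.09 CPM in MLE12 (-8.06 ± 0.12). Trp53 was slightly higher in LLC1 (187 ± 9.25 against 153 ± 5.21 CPM; 0.30 ± 0.04) and Rb1 higher in MLE12 (-1.06 ± 0.08). The 23 lung cancer oncogene and tumour suppressor genes comprised 9 higher in LLC1, 14 higher in MLE12 and 0 not called (9 and 14 adjusted over the list alone). The list median was -0.22 (camera adjusted p = 0.426). The receptors Fgfr1 (406 ± 20.3 CPM in LLC1 and 1.21 ± 0.534 CPM in MLE12; 8.47 ± 0.17) and Egfr (3.81 ± 0.11) were higher in LLC1. Receptor tyrosine kinase genes as a list were not called (camera adjusted p = 0.671), with 13 higher in LLC1, 15 higher in MLE12 and 1 not called (14 and 15 adjusted over the list alone) and a median of -0.45. Pdgfra (5.71 ± 0.17) was higher in LLC1, and Epha4 (-8.49 ± 0.09) and Ror1 (-8.06 ± 0.12) higher in MLE12.

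p53 target genes were more often higher in LLC1, with 19 higher in LLC1, 8 higher in MLE12 and 3 not called (20 and 8 adjusted over the list alone). Their median log2 fold change was 0.59 (camera adjusted p = 0.0410, adjusted p = 0.186 with an estimated correlation). The cyclin-dependent kinase inhibitor Cdkn1a (164 ± 5.60 CPM in LLC1 and 21.0 ± 0.508 CPM in MLE12; 2.97 ± 0.05) and 9030617O03Rik (4.59 ± 0.08) were higher in LLC1. Perp (-8.23 ± 0.12) and Btg2 (-4.32 ± 0.09) were higher in MLE12. E2F target and DNA replication genes were more often higher in MLE12, with 5 higher in LLC1, 29 higher in MLE12 and 6 not called (5 and 29 adjusted over the list alone). The median of the list stood at -0.49 (camera adjusted p = 0.0409, adjusted p = 0.450 with an estimated correlation). Gins2 (-1.73 ± 0.05) and Rfc3 (-1.42 ± 0.05) were higher in MLE12, while E2f8 (1.60 ± 0.05) and Mcm3 (0.50 ± 0.04) were higher in LLC1. With at least 1 CPM required in 4 libraries the adjusted p was 0.0533 for p53 targets and 0.0891 for E2F targets, and without LLC1 replicate 1 it was 0.0507 for each, so that both calls ended. The E2F call also ended without LLC1 replicate 4 (0.0516), and the p53 call without MLE12 replicate 3 (0.0560) and with library totals alone (0.0737). Mitotic genes showed 10 higher in LLC1, 13 higher in MLE12 and 2 not called (10 and 13 adjusted over the list alone). For the list as a whole the median was -0.28 (camera adjusted p = 0.555). Ttk (-1.37 ± 0.05) and Foxm1 (-0.94 ± 0.06) were higher in MLE12, and Ube2c (0.46 ± 0.05) and Aurka (0.44 ± 0.05) were higher in LLC1. YAP and TEAD target genes were split into 10 higher in LLC1, 12 higher in MLE12 and 1 not called (10 and 12 adjusted over the list alone). Their log2 fold changes had a median of -0.12 (camera adjusted p = 0.398). The matricellular genes Ctgf (0.795 ± 0.171 CPM in LLC1 and 130.1 ± 3.10 CPM in MLE12; -7.36 ± 0.08) and Cyr61 (16.7 ± 1.07 CPM in LLC1 and 478 ± 10.1 CPM in MLE12; -4.84 ± 0.05) were higher in MLE12. Arhgef17 (6.38 ± 0.10) and the receptor gene Axl (508 ± 28.3 CPM in LLC1 and 24.8 ± 0.654 CPM in MLE12; 4.36 ± 0.05) were higher in LLC1. Imprinted and oncofetal growth genes were more often higher in LLC1, with 11 higher in LLC1, 3 higher in MLE12 and 3 not called (11 and 3 adjusted over the list alone) among 17 tested. For the list as a whole the median was 1.89 (camera adjusted p = 1.9e-05, adjusted p = 0.0836 with an estimated correlation). The chromatin protein gene Hmga2 stood at 740.2 ± 36.7 CPM in LLC1 and 9.29 ± 1.05 CPM in MLE12 (6.32 ± 0.07). The imprinted gene Peg3 had a log2 fold change of 8.81 ± 0.10, and the RNA-binding protein gene Igf2bp3 (-1.49 ± 0.06) was higher in MLE12.

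Antigen presentation and interferon-stimulated genes were mostly lower in LLC1. The 20 MHC class I presentation genes comprised 2 higher in LLC1, 16 higher in MLE12 and 2 not called (2 and 17 adjusted over the list alone). The list median was -1.65 (camera adjusted p = 1.6e-06, adjusted p = 0.0673 with an estimated correlation). The class I heavy chain gene H2-K1 stood at 19.1 ± 1.39 CPM in LLC1 and 192 ± 11.2 CPM in MLE12 (-3.33 ± 0.06). The immunoproteasome gene Psmb8 was at 0.101 ± 0.0298 CPM in LLC1 and 32.7 ± 2.59 CPM in MLE12 (-8.31 ± 0.14). For H2-Q4 the log2 fold change was -5.06 ± 0.12. H2-T23 (1.72 ± 0.10) was higher in LLC1. B2m, the light chain shared by class I molecules, did not pass the test (185 ± 6.41 CPM in LLC1 and 194 ± 12.2 CPM in MLE12; -0.06 ± 0.05, adjusted p = 0.224). H2 genes resemble one another closely and vary between strains, so the split of reads among them is uncertain. Interferon-stimulated genes counted 2 higher in LLC1, 31 higher in MLE12 and 0 not called (2 and 31 adjusted over the list alone) among 33 tested. Their median log2 fold change was -2.59 (camera adjusted p = 9.4e-07, adjusted p = 0.0559 with an estimated correlation). The RNA sensor gene Ifih1 (-6.78 ± 0.17) and the ubiquitin-like modifier gene Isg15 (0.366 ± 0.0823 CPM in LLC1 and 10.3 ± 1.75 CPM in MLE12; -4.79 ± 0.17) were higher in MLE12. Ifitm1 (7.63 ± 0.20) and Ifitm3 (173 ± 8.07 CPM in LLC1 and 48.0 ± 2.76 CPM in MLE12; 1.85 ± 0.05) were the only members higher in LLC1. Chemokine, cytokine and growth factor genes showed 13 higher in LLC1, 17 higher in MLE12 and 3 not called (13 and 17 adjusted over the list alone). The median of the list stood at -0.51 (camera adjusted p = 0.889). Spp1, which encodes osteopontin, stood at 1116 ± 13.4 CPM in LLC1 and 17.3 ± 1.80 CPM in MLE12 (6.02 ± 0.07). The cytokine gene Il34 (6.87 ± 0.21) was also higher in LLC1, and Inhba (-7.10 ± 0.13) and Tgfb2 (1.74 ± 0.409 CPM in LLC1 and 211 ± 10.2 CPM in MLE12; -6.93 ± 0.09) were higher in MLE12. Immune checkpoint and immunoregulatory genes were not called as a list (camera adjusted p = 0.213), with 9 higher in LLC1, 7 higher in MLE12 and 1 not called (9 and 7 adjusted over the list alone) and a median of 0.38. The prostaglandin synthesis genes Ptgs1 (419 ± 11.2 CPM in LLC1 and 1.85 ± 0.349 CPM in MLE12; 7.85 ± 0.08) and Ptges (7.79 ± 0.07) were higher in LLC1. Cd24a (-7.96 ± 0.12) and Lgals9 (-3.74 ± 0.05) were higher in MLE12. Of 22 leukocyte, endothelial and erythroid markers only 6 had enough counts to be tested, with 1 higher in LLC1, 3 higher in MLE12 and 2 not called (1 and 3 adjusted over the list alone). The median of the list stood at -0.21 (camera adjusted p = 0.889). Csf1r was at 10.5 ± 0.788 CPM in LLC1 and 12.8 ± 1.02 CPM in MLE12 (-0.29 ± 0.08).

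Glycolysis genes were mostly higher in LLC1. Their 23 members comprised 19 higher in LLC1, 3 higher in MLE12 and 1 not called (19 and 3 adjusted over the list alone). Their log2 fold changes had a median of 1.06 (camera adjusted p = 5.9e-07, adjusted p = 0.174 with an estimated correlation). Hexokinase 2, Hk2 (141 ± 3.98 CPM in LLC1 and 13.3 ± 0.454 CPM in MLE12; 3.41 ± 0.05), and the pyruvate dehydrogenase kinase Pdk1 (2.97 ± 0.05) were higher in LLC1, and Pfkfb3 (-0.97 ± 0.07) was higher in MLE12. Nuclear-encoded respiratory chain genes went both ways, with 17 higher in LLC1, 21 higher in MLE12 and 8 not called (17 and 21 adjusted over the list alone). The list median was -0.09 (camera adjusted p = 0.834). Ndufb7 (-1.35 ± 0.06) and Cox6a1 (-1.01 ± 0.05) were higher in MLE12, and Ndufs1 (0.69 ± 0.04) and the succinate dehydrogenase gene Sdha (0.99 ± 0.04) in LLC1. Cholesterol synthesis and uptake genes had 9 higher in LLC1, 15 higher in MLE12 and 1 not called (9 and 15 adjusted over the list alone). Their log2 fold changes had a median of -0.24 (camera adjusted p = 0.398). Ebp (-2.18 ± 0.08) and Hsd17b7 (-1.99 ± 0.06) were higher in MLE12, and Sqle (0.45 ± 0.04) was higher in LLC1. For fatty acid and phospholipid synthesis the counts were 7 higher in LLC1, 16 higher in MLE12 and 1 not called (7 and 16 adjusted over the list alone). For the list as a whole the median was -0.33 (camera adjusted p = 0.403). Pcyt1a (-1.70 ± 0.04) and Fads2 (-1.36 ± 0.05) were higher in MLE12, and Lpin1 (3.54 ± 0.08) and Elovl6 (1.30 ± 0.05) in LLC1. NRF2 target and glutathione genes divided into 14 higher in LLC1, 16 higher in MLE12 and 2 not called (14 and 16 adjusted over the list alone). The list was not called (camera adjusted p = 0.926). The camera direction was toward LLC1 while the median (-0.14) and mean (-0.43) were negative. Aldh3a1 (-7.76 ± 0.24) and Mgst1 (-4.54 ± 0.09) were higher in MLE12, and Gstm2 (2.28 ± 0.08) and Gstp1 (2.77 ± 0.24) in LLC1. Gstp1, which stood at 143 ± 19.2 CPM in LLC1 and 20.9 ± 6.86 CPM in MLE12, is nearly identical to its neighbour Gstp2, so its level is uncertain.

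Xist, the RNA that coats the inactive X chromosome, was present in both lines (833 ± 101 CPM in LLC1 and 1251 ± 20.9 CPM in MLE12; -0.59 ± 0.07). It was the single called gene of the sex chromosome list, of which 2 were tested (0 higher in LLC1 and 1 higher in MLE12 adjusted over the list alone). Of the other list members, chosen after their values were seen, the Y-linked gene Uty did not differ detectably (0.279 and 0.260 CPM; adjusted p = 0.855), and Kdm5d, Ddx3y and Eif2s3y had too few counts to be tested. The genes with the most counts in both lines were Yam1, AY036118 and Lars2, which hold ribosomal RNA-like sequence, followed by the elongation factor Eef1a1 (7967 ± 110.0 CPM in LLC1 and 4571 ± 108 CPM in MLE12; 0.80 ± 0.04). Those 3 took 9.33% to 15% of counts in LLC1 libraries and 9.76% to 10.4% in MLE12 libraries. The positions of Yam1 and AY036118 overlap, so some reads may be counted for both. Yam1 (0.31 ± 0.16, adjusted p = 0.123) and AY036118 (0.33 ± 0.16, adjusted p = 0.0865) did not pass the test. Hsp90ab1 (1.16 ± 0.04) and Eef2 (0.57 ± 0.05) completed the 5 most abundant in LLC1 and MLE12, respectively. By the detection limit set beforehand, 97 genes had at least 1 CPM in every LLC1 library and at most 3 counts over the MLE12 libraries, and 129 met the reverse. These counts depend on the limit and ranged from 14 to 244 and from 17 to 335 under other limits. The highest of these, chosen after their values were seen, were the transcriptional regulator Lmo1 (15.8 CPM in LLC1) and the transcription factor Mef2c (10.3 CPM in MLE12). Among the LLC1-only genes, several alpha-protocadherin gene IDs, also chosen after their values were seen, had the same mean of 1.73 CPM. The same reads may have been counted for several of these IDs, so the 97 may not all be separate genes.

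Fold changes also differed between chromosomes, a comparison made after the data had been seen. Among 8675 genes with at least 10 CPM in both lines, the median log2 fold change was -0.77 on chromosome 8 (504 genes, 84.5% below 0), -0.58 on chromosome 14 and -0.47 on chromosome 16, against 0.37 on chromosome 12 and 0.35 on chromosome 15. Cdh1, Gins2, Mmp2, Ndufb7, Fgfr1 and Il34, named above, lie on chromosome 8. Of these, Cdh1, Mmp2, Fgfr1 and Il34 were under 10 CPM in one line and so not among the genes compared, and Fgfr1 and Il34 were higher in LLC1.

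**Figure D4:**
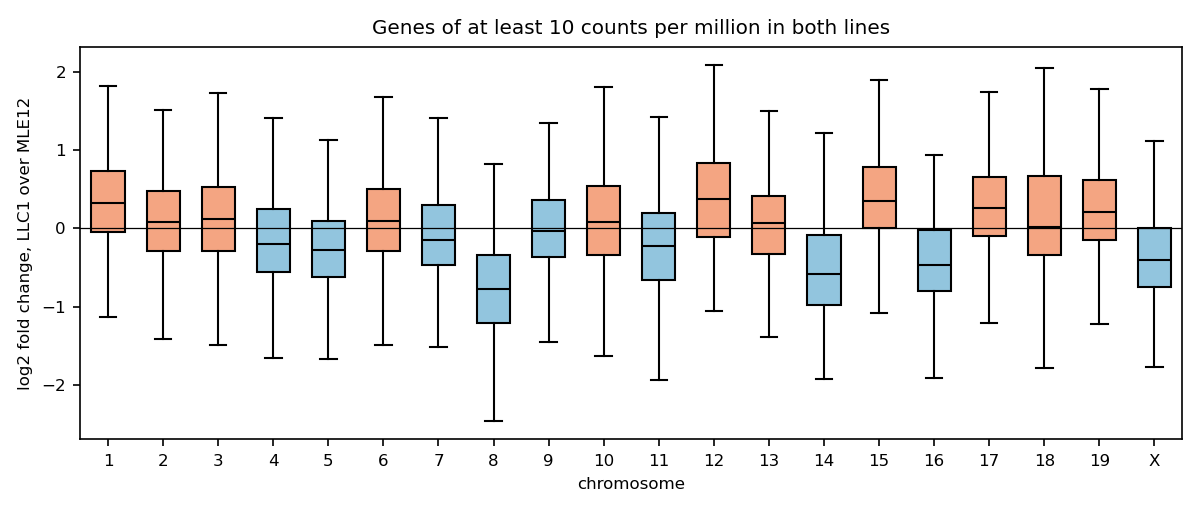
Log2 fold change, LLC1 over MLE12 (y axis), of genes with at least 10 CPM in both lines, by chromosome (x axis); boxes span the quartiles with a line at the median, whiskers reach the furthest gene within 1.5 box heights, and genes beyond are not drawn. Boxes with a negative median are blue and the others orange, and chromosome 8 has the lowest median (-0.77).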

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

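The tests on residual reads and on chromosomes were chosen after the results were seen, and so were the bounds set for the other splits of the libraries.

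The real split of the libraries was set beside the other splits into 4 and 4. Every other split holds libraries of both lines in each group, so the line difference adds to the spread within groups. Few or no calls were therefore likely there from the start, and the comparison cannot decide whether chance gave the differences. The real split called 15132 genes, 6243 of them over 2-fold, and 1 of the 35 splits of the 8 libraries into 4 and 4 (the real one) reached such counts; the other 34 called 0 genes by edgeR, with 8 to 659 genes at an unadjusted p under 0.05. No other tool was run on the splits. For the gene lists the real split called 11 and the highest of the other splits 8, so that 1 of 35 again reached the real value, though camera with the preset correlation called lists in splits that called no gene.

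Outlying libraries were sought in 256 groups of 4 values (123 named genes and 5 library measures in each line). A value was flagged where its gap to the nearest other value was large relative to the range of the 4. Chance gives about 1 in 20 groups, and 18 values were flagged, not far above that share. A flagged value can lie close to the rest, as for Xist in MLE12 (1282 against 1238 to 1242 CPM). MLE12 replicate 4 held 9 of the flagged values. Its total was 48.6 M counts against 72.5 to 76.7 M in the other MLE12 libraries. In that library CPM stood high for Gng2 (0.160), Mpzl2 (100.6), Col3a1 (4.14), Fgfr1 (2.00), Tgfb2 (227) and Xist (1282) and low for Foxm1 (167) and Eef2 (2371). In MLE12 replicate 1, H2-Q4 (44.1 CPM) and Gstp1 (31.2 CPM) were high and Cdh2 (79.4 CPM) was low. Sdha was low in MLE12 replicate 2 (120.3 CPM), and Ndufs1 was high in MLE12 replicate 3 (101 CPM). Among LLC1 libraries, Epha4 was high in replicate 1 (0.370 CPM), and replicate 4 was low for Clic5 (0.114 CPM) and Lgals9 (8.41 CPM) and high for Pdk1 (173 CPM).

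Genes abundant in one line were never absent from the other: of 2432 and 2094 genes with at least 100 CPM in MLE12 and LLC1, the lowest shares were 0.301% in LLC1 and 0.171% in MLE12, near the median residual shares of 0.374% and 0.232%. Among genes of at least 50 CPM the shares reached lower, to 0.223% in LLC1 (Trabd2b) and 0.105% in MLE12 (Apbb1ip), so no common lower edge was shown and low transcription in the line itself stays open. The residual share rests on the 25 lowest genes per library and may include such transcription. The shallower MLE12 replicate 4 held the highest Col3a1, Fgfr1 and Gng2 of its line. Col3a1 and Fgfr1 had low shares of the kind measured (0.183% and 0.297% of the LLC1 level), so they add no separate support. Gng2 lay near the floor (0.160 CPM). The residual share was 0.336% to 0.431% in LLC1, 0.212% to 0.239% in MLE12 replicates 1 to 3 and 0.373% in MLE12 replicate 4. Across libraries the share varied 2.04-fold, but its product with the library total varied 1.29-fold, as a like number of reads assigned to the wrong library during sequencing would give; such reads are a candidate explanation. RNA or cells of the other line mixed in before the libraries were made stay open, because each library may carry its own share: MLE12 replicate 4 stood at 1.66 times the mean of its fellows, close to the 1.53-fold difference in totals.

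The median fold change differed between chromosomes, from -0.77 on chromosome 8 to 0.37 on chromosome 12. A chance arrangement of genes along the genome is argued against: the SD of the chromosome medians was 0.321, above the highest (0.128) of 1000 permutations in which blocks of 20 neighbouring genes were shuffled (permutation p = 0.001, the smallest these draws can give). GC content and gene length do not account for it either, since chromosome 8 stayed at -0.73 after genes of like GC content and length were centred (8625 of the 8675 genes had both). The shift ran along chromosome 8, with 84.5% of its genes below 0 and all 7 windows of 20 Mb below 0 (medians -0.97 to -0.54), so a different number of copies of the whole of chromosome 8 is a candidate explanation, as a hypothesis. For chromosome 12 it is argued against as the whole source, because the shift ended at 80 Mb: the 4 windows before had medians of 0.33 to 0.92, and the last 2 had -0.0013 and -0.02 (66 genes, 95% interval up to 0.122). On chromosome 11 the 3 windows from 80 Mb had medians of -0.55, -0.42 and -0.52, and the 4 before them -0.09 to 0.18. A shift along the whole length was not particular to chromosome 8. All windows of at least 20 genes also lay below 0 on chromosomes 14, 16 and X (78.8%, 76.4% and 74.9% of genes below 0). On chromosomes 1, 15, 17 and 19 all such windows lay above 0 (27.5%, 25.1%, 31.1% and 33.8% of genes below 0). Copies of these chromosomes, and of parts of chromosomes, were not tested. No DNA was measured, and regulation along a chromosome was not tested.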

How the results depend on the processing

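The residual-read subtraction and the detection limit relative to the other line were chosen after the data had been seen. Of 3397 values recomputed for 190 results, 3349 were classed as unchanged and 0 as reversed. For gene counts unchanged meant within 1.5 times the reported count, and for genes and lists the same call. A change of direction without a call in either fit was classed as unchanged, as for the NRF2 list with fry. Named genes gave 2855 of the values, and many were chosen for large changes, so their agreement was likely beforehand. Over the alternatives, genes higher in LLC1 numbered 6478 to 8609 and genes higher in MLE12 6390 to 8817 (over 2-fold, 2375 to 3807 and 2466 to 3897), all within 1.5 times the reported counts (without MLE12 replicate 4, 7744 and 7678); the low ends came from the filter of 1 CPM in 4 libraries and the high ends from no filter, which test fewer and more genes. Of 159 named genes 3 gained a call: B2m passed with library totals alone (-0.16) and without a filter (-0.10), Yam1 without LLC1 replicate 4 and with limma-voom, and AY036118 under 5 settings; the cause was not tested. The replicate numbers showed no clear pairing of the libraries. Deviations of same-numbered libraries correlated at -0.01, 0.11, 0.08 and -0.06, and the highest with another number were 0.07, 0.05, 0.04 and 0.04. These values are mixed and do not exclude a weak pairing. With the numbers as a block 7380 and 7415 genes were called (3057 and 3106 over 2-fold).

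The p53 target list lost its call with DESeq2 size factors (adjusted p 0.0523), library totals alone (0.0737), 1 CPM in 4 libraries (0.0533) and without the 20 most abundant genes (0.0507), and ranged from 0.0315 to 0.0560 with single libraries left out (4.2e-08 to 0.186 over all alternatives). The E2F target list lost it with upper-quartile factors (0.0519) and 1 CPM in 4 libraries (0.0891), and ranged from 0.0305 to 0.0516 with single libraries left out (1.8e-07 to 0.450 over all alternatives). The matrix protease list gained a call after residual-read subtraction (0.0392; its alternatives ranged from 1.4e-06 to 0.551). The cause was not tested for these. With an estimated correlation, 10 lists lost their call: alveolar type II 0.174, epithelial 0.0771, mesenchymal 0.0879, lung transcription factors 0.331, E2F 0.450, p53 0.186, MHC class I 0.0673, interferon-stimulated 0.0559, glycolysis 0.174 and imprinted 0.0836. Why they lost it was not tested. The fry test, which asks whether members move on balance one way and does not compare them with other genes, called 12 further lists: airway 1.5e-06, matrix protease 1.4e-06, mitotic 2.7e-05, oncogenes 4.6e-08, chemokines 0.000582, checkpoint 4.5e-07, cholesterol 6.3e-08, fatty acid 9.9e-06, YAP 2.6e-06, receptor kinases 0.000690, integrins 6.3e-05 and leukocyte markers 0.000553. Genes detected in LLC1 only fell from 97 to 14 at 5 CPM and 32 with no count in MLE12, and rose to 244 with at most 0.6% of the LLC1 level; those detected in MLE12 only went from 129 to 17, 25 and 335. With single libraries left out they ranged from 98 to 122 and from 134 to 173. Leaving out a library can only keep or add genes under this rule, so these ranges could not have shown a loss. Depth and the counts left in the other line, whatever their source, limit this number. Gene IDs that may share reads, as among the alpha-protocadherins, may raise the LLC1 number.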

Other observations

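The Hox genes were chosen as a family after their values were seen. Of 39 annotated Hox genes, 27 were tested, with 19 higher in LLC1, 6 higher in MLE12 and 2 not called. All 6 tested HoxD genes, on chromosome 2, were higher in LLC1, and none exceeded 0.154 CPM in MLE12. Hoxd8 stood at 39.0 CPM and Hoxd9 at 26.4 CPM in LLC1. Hoxd4 lies within the span of Hoxd3, so reads may be shared between them. The HoxA genes divided into 8 higher in LLC1 and 2 higher in MLE12 of 10 tested, with Hoxa7 at 23.4 CPM in LLC1 and 4.32 CPM in MLE12 and Hoxa10 at 5.90 and 15.3 CPM. HoxB genes went both ways, with 3 higher in LLC1, 4 higher in MLE12 and 2 not called.

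Around Cdkn2a, genes chosen after their values were seen, Mtap (chromosome 4, 89137122 to 89181081) stood at 104 ± 6.11 CPM in LLC1 and 112 ± 4.44 CPM in MLE12 (log2 fold change -0.11 ± 0.05), while Cdkn2a and Cdkn2b, which start at 89274471 and 89306289, were at residual level in LLC1. Near Myc on chromosome 15, genes also chosen after their values were seen, differences were uneven. The long noncoding RNA Pvt1 had a log2 fold change of 4.52 ± 0.06 and Asap1 of 2.31 ± 0.05, while Fam49b, between them, had 0.28 ± 0.05 and Efr3a, beyond Asap1, had 0.47 ± 0.04. On the other side Fam84b had -5.21 ± 0.08, Trib1 -0.28 ± 0.05, Nsmce2 0.60 ± 0.05, E430025E21Rik 0.22 ± 0.04 and Sqle 0.45 ± 0.04.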
